A study of Drosophila melanogaster with 44 samples.

How the data were processed

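Omni-ATAC-seq libraries were made from whole brains of 1 male and 1 female fly per line, in 44 DGRP lines, per the labels. The submitters' processing notes name FastQC 1.1.2, Bowtie2 2.2.6, MACS2, Subread 1.4.6, DESeq2 and the genome build dm6, without their roles, order or settings. How reads were shifted for the transposase, filtered or called as peaks, and whether peaks were called per library or on pooled libraries, is not given in the sources used here.

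The deposited accessibility values are a signal, namely read counts per region that the authors divided by 1 size factor per library and rounded to 1 decimal; this was read from the values, since no header states it. Within each library 99.9963% of values on average were whole multiples of the value of 1 read within a tolerance of 0.0525 units of the deposited value, so reads were recovered by division. For 41 libraries the recovery passed a stricter check, and for DGRP_25201, DGRP_28239 and DGRP_28260 it did not, because rounding is large beside the step or the smallest value is not 1 read. The second deposited table holds allele calls at variants inside the regions, per the file headers, coded reference, alternative or no call; the variant caller is not given in the sources used here. Every variant in it is a single-base change. Its 44 accessibility columns repeat the first table and were not used. The genotype column DGRP_55026 was matched to the line labelled DGRP_55026_s2. The number of columns of per-sample values without a matching sample was 0. Gene names and positions came from a RefSeq gene table of the same genome release, without strand, exons or sequence, and coordinates are 1-based.

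Recovered reads over all regions ranged from 0.833 to 7.41 M (mean 4.16 M, SD 1.69 M). One read was worth between 0.472 and 4.53 units of the deposited value. Intervals are exact binomial at 95% for shares of regions. They cover counting error only and treat regions as independent, which linked regions are not.

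The main scan used log2(value + 2), with a pseudocount of 2, and no filter on low values beyond the deposited regions. The design written before the data were examined named edgeR's quasi-likelihood test on counts with TMM; because the deposited unit is normalised, the fallback named there, limma (3.58.1, R 4.3.3), was the main test, and edgeR (4.0.16) on recovered reads an added alternative. A variant needed at least 5 lines per base and at most 9 lines without a call, which 113810 variants met; 146036 had no line with the alternative base. Variants with the same genotypes in a region were tested once. The first 3 principal components of log2 accessibility were covariates, the smallest p per region was multiplied by the number of patterns tested in it, and regions were adjusted by Benjamini-Hochberg at 0.05. No variant could be tested in 2261 regions. The regression was tested on simulated data, with reads drawn for the real regions and libraries and 50 regions changed at each size. Over 18583 regions tested it recovered 10% of regions at 1.25-fold, 66% at 1.5-fold, 92% at 2-fold and 100% at 3-fold, and 4 of its calls were false (2.90% of calls). edgeR recovered 10%, 68%, 92% and 100%, with 4.26% of its calls false. With 200 regions changed, the adjusted threshold was stricter than in the real scan, so these rates do not give its power.

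Directions were tested with exact binomial and Fisher's exact tests, distances of lead variants with 100000 resamples, classes and gene lists with Fisher's exact tests against all tested regions, and distances between lines with a Mantel test of 10000 permutations. The 19 lists held 681 names, of which 14 matched no gene: fast neurotransmitters, monoamines, neuropeptides, ion channels, synapse, mushroom body, neuronal identity factors, temporal factors, glia, clock, adhesion, detoxification, immunity, retina, fat body, muscle, hemocytes, trachea and housekeeping. Named regions were chosen by a rule written before the data were examined. It took the 13 caQTL regions of smallest p in each direction, 1 per nearest gene, with the same direction without principal components and with every single line left out. It added up to 3 caQTL regions per list and the 10 most variable regions among those above the median mean. The measure of variability planned was edgeR's biological coefficient of variation; the coefficient of variation of the deposited values took its place for the same reason as above. Gene starts and exons were replaced by gene boundaries and bodies, and the planned test of sequence motifs and the check of reference bases were not run because no genome sequence was used here.

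Alternatives planned beforehand covered the number of components, log10 reads as covariate, normalization, a rank test, DESeq2 (1.42.0) at the named regions, limits on lines per base, a filter on low counts, the 11 lines of fewest reads, single lines left out, other-tissue scores, the assignment of regions to genes, ties and, for distances between lines, a pseudocount of 0.5. Alternatives chosen after seeing the data were edgeR on recovered reads, pseudocounts of 0.5 and 10 in the scan, the blocks of the sample list, scans without DGRP_28202 or without the libraries labelled DGRP_25185 and DGRP_29651, distances without the 2 lines farthest in genotype, and logistic models. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.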

Results

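Chromatin accessibility was measured by omni-ATAC-seq in whole brains of 44 inbred lines of the Drosophila Genetic Reference Panel (DGRP). The DGRP is a set of fruit fly (Drosophila melanogaster) lines, each inbred from a wild-caught female until nearly homozygous, so that 1 line stands for 1 genotype. In ATAC-seq a transposase cuts open chromatin, and the number of reads in a region measures how accessible it is. Per the labels, each library held the brains of 1 male and 1 female fly aged 1 to 3 days. All 44 libraries formed 1 group, with 1 library per line and no replicate library of any line. The p-values of limma and of permutations of the lines therefore measure the spread between lines, which includes technical variation. Exact binomial tests, Fisher's exact tests, logistic models and permutations of regions instead take regions or genes as units. Their p-values treat linked regions as independent and do not measure the spread between lines. Accessibility was given as normalised read counts in regions covering 12.2 Mb of the genome (dm6, median width 505 bp), 18583 with a variant that could be tested and 2261 without, beside allele calls at 413274 single-base variants inside them. The reads recovered per library ranged from 0.833 M in DGRP_28238 to 7.41 M in DGRP_29651 (median 4.09 M), and the number of regions without a read ranged from 2 to 234. The design implies 1 main question: at which regions accessibility in the adult brain differed between carriers of the reference base and carriers of the alternative base of a variant inside the region.

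The libraries had similar profiles: each line's median Spearman correlation with the others lay between 0.856 and 0.928. The sample list runs in ascending stock number and starts over at 2 places, which leaves 3 parts of 4, 16 and 24 lines, here called blocks 1, 2 and 3. The first principal component held 32.3% of the variance, and 83.4% of its variance lay between the blocks (permutation p = 0.0001, the smallest that 10000 permutations can give). The third component held 4.72% of the variance and set block 1 apart, with 67.96% between blocks (permutation p = 0.0001). Of the 19 gene lists fixed beforehand, 4 had block medians that lay furthest apart, given here as log2 accessibility relative to all regions in blocks 1, 2 and 3, without a test. Synaptic genes had 0.85, 0.45 and 0.55, housekeeping genes 0.14, -0.26 and 0.06, innate immunity genes -0.36, -0.53 and -0.30, and fat body markers, of another tissue, -0.0071, -0.21 and -0.063. The 1% of regions with the most reads held a median of 9.13%, 11.2% and 8.80% of the reads in the 3 blocks. The labels name no batch. The share of reads on the X chromosome had a median of 15.6% and was lowest in DGRP_28202 (11.2%) and highest in DGRP_28123 (18.2%).

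**Figure D1:**
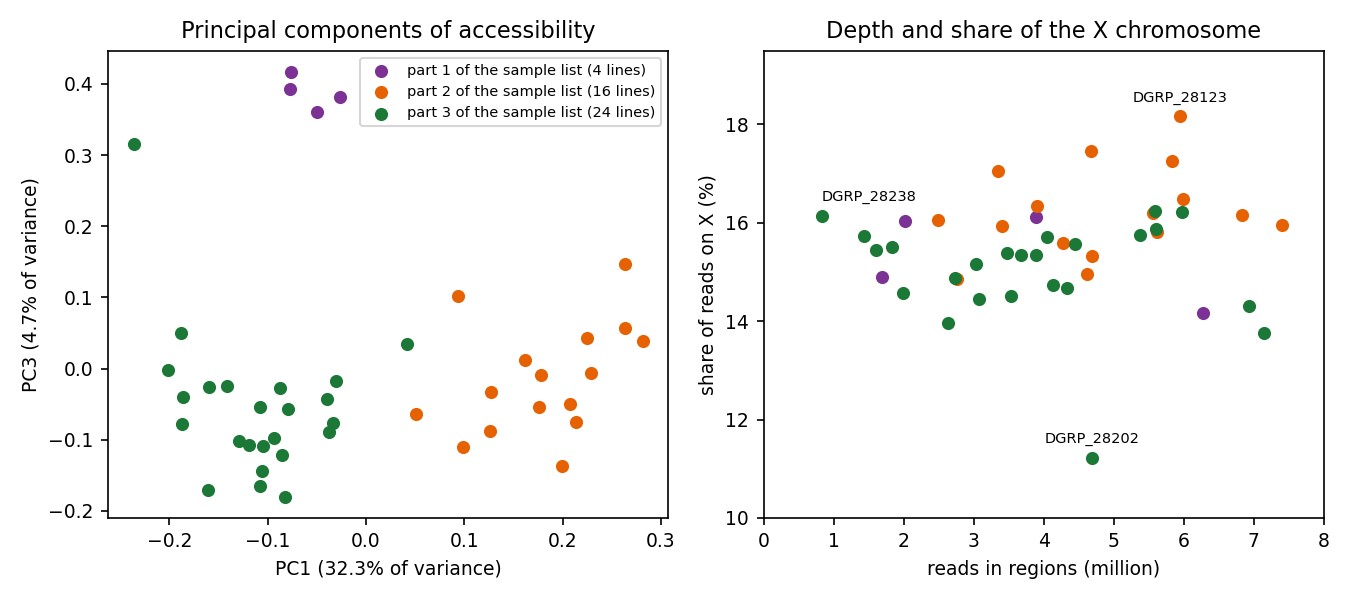
Left, each of the 44 lines by its value on principal components 1 and 3 of log2 accessibility, coloured by part of the sample list. Right, each line by its reads in regions (M) and the share of those reads on the X chromosome (%); DGRP_28202 lies lowest at 11.2%, and DGRP_28238 has the fewest reads at 0.833 M.

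Accessibility was associated with a variant inside the region at 2216 of 18583 regions tested, or 11.9% (exact binomial 95% interval 11.5% to 12.4%). Such a region is called a caQTL region here, for chromatin accessibility quantitative trait locus. The base that differs from the reference genome went with lower accessibility at 1470 of these regions and with higher accessibility at 746. The share with a lower alternative base was 66.3% (interval 64.3% to 68.3%, two-sided exact binomial p = 3.48e-54), against 54.8% at the 16367 tested regions outside the call (Fisher's exact test, odds ratio 1.63, p = 2.26e-25). Effects were mostly moderate, with a median of 1.41-fold where the alternative base was lower and 1.39-fold where it was higher. At least 2-fold differences were found at 95 regions with the alternative base lower and 40 with it higher, and at least 4-fold differences at 16 and 1. The lead variant accounted for a median of 34.2% of the variance left after 3 principal components. These sizes come from the same lines that chose the regions and lead variants, which tends to overstate them. The scan tested 104417 genotype patterns with limma's moderated regression on log2(value + 2), and fold changes are on that scale, which understates changes of low regions. Without principal components 1159 regions were called, of which 1032 were among the 2216. Without the libraries labelled DGRP_25185 and DGRP_29651, described further down, 2359 regions were called and 66.6% had the alternative base lower.

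The share with a lower alternative base fell as that base became more common. Where up to 20% of the lines with a call carried it, 75.3% of 586 caQTL regions had it lower (interval 71.6% to 78.7%). The share was 68.5% for 20% to 40% of lines, 59.7% for 40% to 60% (interval 55.2% to 64.03%) and 58.2% for 60% to 80%. Where over 80% of lines carried it, the share was 46.9% of 64 regions (interval 34.3% to 59.8%). Alternative bases carried by up to 50% of lines were lower more often than those above 50% (69.2% against 58.3%, Fisher's exact test, odds ratio 1.604, p = 3.04e-06). A fall also arose when the genotypes were dealt at random to other libraries, in 99 drawn pairings looked at by frequency after the data were seen. Among the 2216 regions of smallest p in each, the share fell from a median of 57.7% in the first of the 5 bins to 42.1% in the last. The odds ratio across 50% of lines had a median of 1.498 (1.15 to 1.80) in the drawn pairings. Of 100 pairings, the real one included, 20 reached the real 1.604, so this contrast does not tell the real pairing from the drawn ones. In a logistic regression, the odds of a lower alternative base changed by a factor of 0.852 per 10 points of its frequency in the real pairing and by 0.879 to 0.955 in the drawn ones. The real share was higher than in every drawn pairing in each bin but the last. The share also differed with how many more alternative bases in the region, the lead included, the alternative lines carried on average than the reference lines. It was 60.3% where this rounded number was at most 1 (630 regions, interval 56.4% to 64.2%) and 80.1% where it was 9 or more (151 regions, interval 72.9% to 86.2%).

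**Figure D2:**
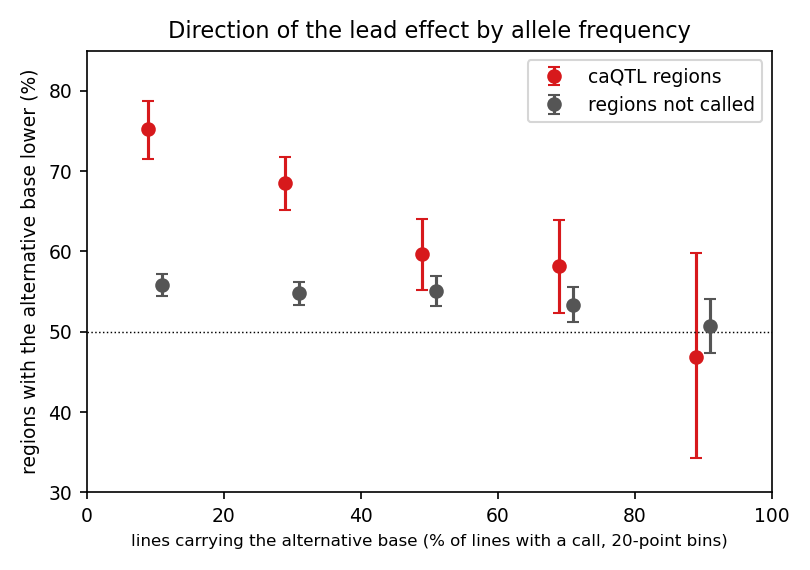
Percent of regions in which the alternative base had the lower accessibility, by the percent of lines that carry it in 20-point bins, for caQTL regions (red) and regions not called (grey). Bars are exact binomial 95% intervals; the caQTL share falls from 75.3% to 46.9%, while the share at regions not called stays between 50.7% and 55.8%.

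The region with the smallest p among those with a lower alternative base lay inside Eip63F-1, which encodes a calcium-binding EF-hand protein (3L, 3921329 to 3921780). Its normalised read count was 87.4 ± 28.7 (SD, n = 31 lines) with the reference base and 9.02 ± 5.01 (n = 12) with the alternative base, a log2 difference of -3.19 ± 0.21 (SE, limma, adjusted p = 1.52e-15). A region inside scrib, which encodes a scaffold protein of cell polarity (3R, 26553025 to 26554024), fell from 417 ± 86.4 (n = 33) to 96.8 ± 15.4 (n = 5; adjusted p = 5.74e-14 by limma). At tin, a homeobox gene of heart and muscle development (3R, 21380415 to 21380946), the count was 198 ± 95.7 (n = 33) with the reference base and 32 ± 8.41 (n = 8; adjusted p = 4.18e-13 by limma). At slou, another homeobox gene, the log2 difference was -1.20, and at nrv2, which encodes a beta subunit of the sodium pump, it was -1.58. The region at Eglp4, of the aquaporin family, had 135 ± 77.2 (n = 14) against 13.8 ± 7.04 (n = 27). The remaining 7 of the 13 named regions with a lower alternative base lay nearest to CG15531, CG8003, CG14130, CG42524, fok, IntS1 (a subunit of the Integrator complex) and PIG-T (a subunit of the GPI transamidase), with log2 differences of -2.20, -2.10, -2.76, -1.19, -0.995, -1.61 and -1.47. At CG8003, 8 variants had the same genotypes over the lines and could not be separated, and at IntS1, 5.

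Among regions with a higher alternative base, the smallest p belonged to a region 28 bp from CG40439 (2L, 22798121 to 22798486). It held 9 reads over 29 reference lines, 24 of which had none, and 894 reads over 11 alternative lines. The normalised read counts were 0.286 ± 0.715 and 79.4 ± 44.6, and the log2 difference was 4.98 ± 0.26 (SE, limma, adjusted p = 1.04e-18). A region inside KCNQ, which encodes a voltage-gated potassium channel (2R, 10186541 to 10187288), rose from 92.9 ± 10.8 (n = 13) to 161 ± 26.8 (n = 27), and 1 inside Elk, another potassium channel gene (2R, 17922791 to 17923635), from 231 ± 58.7 (n = 11) to 398 ± 78.6 (n = 31). A region inside CadN, the gene of N-cadherin (2L, 17662381 to 17662993), rose from 46.8 ± 11.02 (n = 23) to 114 ± 28.1 (n = 13). A region inside Dop1R2, a dopamine receptor gene (3R, 29651074 to 29651703), rose from 88.3 ± 35.4 (n = 16) to 169 ± 52.3 (n = 25), and 1 at CrzR, the corazonin receptor gene (3L, 12351420 to 12351899), from 86.03 ± 40.3 (n = 8) to 164 ± 45.2 (n = 34). Their adjusted p by limma lay between 1.63e-11 at KCNQ and 1.70e-07 at Elk. A region inside N, the gene of the Notch receptor, had a log2 difference of 1.22, and 1 inside kay, the fly gene of the AP-1 protein Fos, 0.98. The other 5 lay nearest to CG1894, CecC (a cecropin), Obp56g (an odorant-binding protein), Tehao (a Toll family receptor) and msopa, with log2 differences of 1.07, 0.66, 0.95, 0.75 and 0.83. Of these 26 regions, 25 passed the threshold in each setting in which their lead variant was tested, and CecC missed it in the 20 lines of blocks 1 and 2. The rank test was applied to the scan as a whole and was not read at the named regions. In 1 or more settings 13 of the 26 could not be tested, 11 of them in blocks 1 and 2 and 6 in block 3. There they had too few lines per base or too many without a call, a limit lowered with the number of lines.

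**Figure D3:**
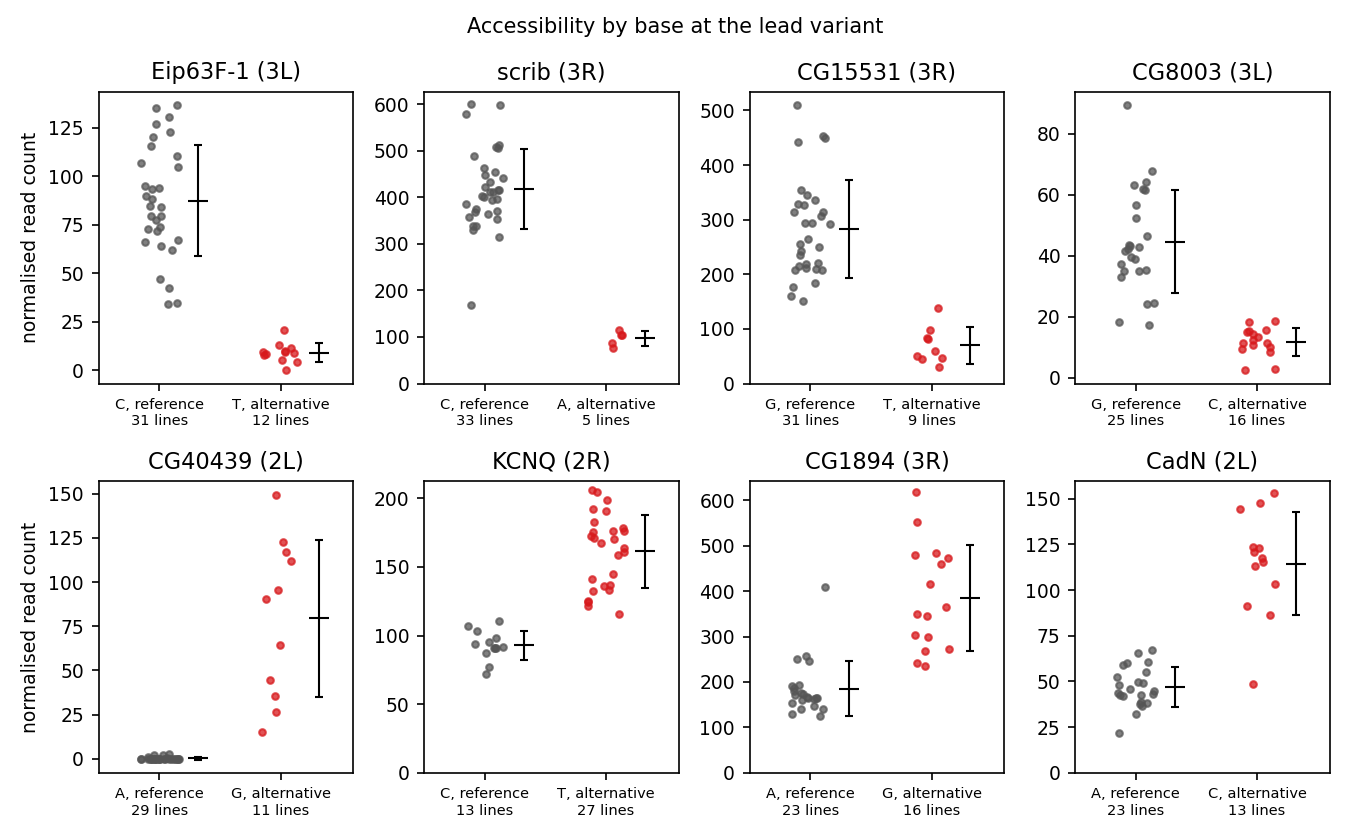
Normalised read count per line (points) by base at the lead variant, for the 4 regions of smallest p with the alternative base lower (top) and the 4 with it higher (bottom). Black marks are mean ± SD over lines; at Eip63F-1 the mean is 87.4 with the reference base and 9.02 with the alternative base, and at CG40439 it is 0.286 and 79.4.

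The 19 gene lists fixed beforehand were compared with all tested regions, a region counting for each gene whose body, widened by 5 kb, held its midpoint. No list passed the adjusted threshold (Fisher's exact tests, Benjamini-Hochberg over 19 lists), and at an unadjusted p under 0.05 only the retina list did. Of 43 regions tested at genes of fast neurotransmitters, 7 were called (9 adjusted over the list alone), 3 with the alternative base lower. At VGlut, the vesicular glutamate transporter, the count was 730 ± 88.03 (n = 33) against 592 ± 90.1 (n = 6), at Ace, the acetylcholinesterase gene, the log2 difference was 0.56, and at a region 75 bp from wit, counted for Gad1, the gene of GABA synthesis, -0.51. Of 161 regions at monoamine genes, 23 were called (24 adjusted over the list alone), 11 lower and 12 higher. Besides Dop1R2 these included the serotonin receptor gene 5-HT2B (145 ± 22.9, n = 38, against 79.7 ± 15.1, n = 5) and Dop1R1 (64.2 ± 12.2, n = 33, against 104 ± 23.3, n = 7). Neuropeptide and receptor genes had 30 of 227 regions called (34 adjusted over the list alone), 20 of them lower. CCHa1 (log2 difference 1.08 at a region nearest to Npc2b) and the diuretic hormone receptor gene Dh44-R1 (0.81) were among those with a higher alternative base. Ion channel genes had 35 of 350 (34 adjusted over the list alone), 20 lower. With KCNQ and Elk these included Shal, a potassium channel gene, at 222 ± 53.9 (n = 28) against 124 ± 27.7 (n = 11).

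At genes of the synaptic vesicle and active zone 8 of 96 regions were called (5 adjusted over the list alone), 7 of them with the alternative base lower. Examples were Syt1, the calcium sensor of vesicle release (log2 difference -0.85), Rim (-0.47, at a region inside tinc) and Rop (-0.35, at a region inside ens). The Syt1 call was lost without DGRP_55031, and the Rop call without DGRP_25193. Mushroom body and memory genes had 31 of 253 regions called (32 adjusted over the list alone), led by Dop1R2 and mub (-0.75), and neuronal identity transcription factors had 20 of 231 (15 adjusted over the list alone), led by pdm3 (-0.50), CG12605 (-0.89, outside the gene) and Ets65A (-0.68, at a region inside l(3)mbn). Temporal and maturation transcription factors had 25 of 257 (25 adjusted over the list alone). At Syp, an RNA-binding protein gene, 2 regions rose by log2 differences of 0.98 and 0.54, and a region at EcR, the ecdysone receptor gene, fell by 0.42.

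Glial genes had 12 of 112 regions called (12 adjusted over the list alone), 8 lower. At Gli, the gliotactin gene (2L, 15762365 to 15762880), the count was 93.5 ± 49.8 (n = 35) with the reference base and 308 ± 34.6 (n = 6) with the alternative base (limma, adjusted p = 3.10e-05). A region inside Trx2, counted for gcm2, a gene of glial fate, had a log2 difference of -0.40. Circadian clock genes had 12 of 88 called (13 adjusted over the list alone), among them vri (-1.24) and Pdp1 (-0.73), both transcription factors of the clock, and qsm (0.37). Adhesion and wiring genes made up the longest list, with 133 of 1048 regions called (135 adjusted over the list alone), 83 lower, at 54 of 92 genes. Besides CadN, a region inside Nlg4, a neuroligin gene, fell from 776 ± 254 (n = 36) to 306 ± 51.4 (n = 6). A region inside side-VI, of the Sidestep family, had 135 ± 27.5 (n = 37) against 40.9 ± 59.4 (n = 6), a log2 difference of -2.85, and of -3.48 without the library labelled DGRP_29651, with or without DGRP_25185. With genes in place of regions as the unit, 6 of the 19 lists passed the adjusted threshold, a comparison that leaves the number of regions per gene unadjusted.

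Detoxification genes had 7 of 73 regions called (7 adjusted over the list alone), among them Ugt303A1 (log2 difference -0.62, 4756 bp from a boundary), Cyp12a4 (1.28, inside Ppcs) and the GstE cluster of glutathione S-transferases (0.80, outside the genes). Innate immunity genes had 7 of 89 (2 adjusted over the list alone), among them dl (-0.45, outside the gene) and Rel (0.71, inside Mst85C and Nmdmc), both of the NF-kappa-B family, and the receptor gene Tl (0.24), which passed the threshold in 29 of 44 scans with 1 line left out. Markers of other tissues were included because a dissected brain can carry retina, fat body, muscle, trachea or hemocytes. Retina markers had 4 of 105 regions called (2 adjusted over the list alone), an odds ratio of 0.291 (Fisher's exact test p = 0.00614, adjusted p = 0.117), with inaD at 0.85 (inside CG13531), norpA at 0.42 (183 bp from a boundary) and Galphaq at -0.39 (nearest to CG45086). Fat body markers had 5 of 30 (5 adjusted over the list alone), with Ilp6 at -0.59 (inside Raf), FASN1 at -0.31 (inside the gene) and Lsp1alpha at -0.41 (nearest to mdu). Muscle markers had 2 of 32 (2 adjusted over the list alone), TpnC47D at -0.72 (inside Vhl) and Mlc1 at 0.47 (inside tau). Hemocyte markers had 8 of 46 (11 adjusted over the list alone), including 3 counted for Pxn, 1 inside it (0.65), 1 inside CG42245 and MEP-1 (-0.57) and 1 nearest to CG42245 (-0.74). Trachea markers had 0 of 18 (0 adjusted over the list alone). Housekeeping genes had 6 of 67 (6 adjusted over the list alone), including 2 counted for Cam, the calmodulin gene, 1 inside it (-0.91) and 1 nearest to CG13168 (-0.62), and 1 for His2Av (-0.76, inside Lerp). Retina markers were least accessible in DGRP_28238, 5.11 robust SD below the median line and 1 of 3 lines beyond 3 robust SD. Trachea markers also lay lowest there at -3.22 robust SD. DGRP_28238 had the fewest reads (0.833 M), and whether low depth shaped these scores was not tested. With the other-tissue scores as covariates 1751 regions were called. Without principal components, 18 of the 71 named regions missed the threshold, all of them list regions. They were the regions counted for VGlut, Ace, Rim, Rop, pdm3, Ets65A, EcR, gcm2, Rel, Tl, norpA, Galphaq, Ilp6, FASN1, Lsp1alpha, Mlc1 and 2 of the regions at Pxn.

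caQTL regions were less common near gene boundaries, meaning either end of an annotated gene, since the gene table used has no strand. Within 500 bp of a boundary 443 of 4880 regions were called (9.08%, odds ratio 0.672, Fisher's exact test, adjusted p = 2.71e-12 over 9 classes). Inside gene bodies away from the boundaries 12.7% of 9356 regions were called (odds ratio 1.16, adjusted p = 0.00213), and between genes 13.4% of 4347 (odds ratio 1.20, adjusted p = 0.00153). On the X chromosome 256 of 2765 regions were called (9.26%, odds ratio 0.721, adjusted p = 6.89e-06), and on 2L 13.4% of 3768 (odds ratio 1.19, adjusted p = 0.00290). With the number of tests, mean accessibility and width of the region in a logistic model, the odds ratio was 0.630 near boundaries (adjusted p = 3.89e-15), 0.845 on X (adjusted p = 0.0391) and 1.06 on 2L (adjusted p = 0.428). Lead variants lay closer to the middle of the region when it was called, at a mean of 125 bp ± 109 (SD) from the midpoint against 152 bp ± 128 in regions outside the call (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give).

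The blocks of the sample list were also scanned apart. Block 2 includes the libraries labelled DGRP_25185 and DGRP_29651, which fit another genotype better than their own (below), and these scans kept them. In block 3 alone (24 lines), 834 regions were called, of which 735 could be tested at the same variant in the other 20 lines. The direction was the same in 685 of them (93.2%, interval 91.1% to 94.9%), and 274 (37.3%) passed an adjusted p of 0.05 there. The median absolute log2 difference was 0.654 in block 3, and the median in the same direction was 0.326 in the other 20 lines. In blocks 1 and 2 together, 170 regions were called, and 153 of the 156 that could be tested had the same direction in block 3 (98.1%), 106 of them past the threshold. Here the medians were 0.712 in blocks 1 and 2 and 0.527 in block 3.

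Between lines, the normalised read count of a region had a median coefficient of variation of 28.2% (5th to 95th percentile 16.3% to 52.8%), while counting error alone would give a median of 10.8%. Line differences and technical variation cannot be separated without replicate libraries. Among the more accessible regions, the most variable was 586 bp from mthl8, a gene of the methuselah family of receptors (3L, 26518 to 27270), with counts from 0 to 858 and a coefficient of variation of 130%. The next were a region inside pb, the homeotic gene proboscipedia (104%, a caQTL region with a log2 difference of -2.19), and a region nearest to CG43149 (3L, 39947 to 40844, 95.8%). The other 7 of the top 10 lay at CG13731, chic (the profilin gene), GstE3, ftz-f1 (a nuclear receptor gene), moody (a glial receptor gene), gl (the glass gene of photoreceptors) and CG9380, with coefficients from 71.7% to 90.2%. Of these 7, the GstE3 region was a caQTL region.

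Pairs of lines differed at a median of 13.1% of variants. Without removal of principal components, no relation between genotype distance and accessibility distance was detected over 946 pairs of lines, with a Spearman correlation of 0.023 (Mantel permutation of the lines, p = 0.275) and a Pearson correlation of -0.0080 (permutation p = 0.630). Without the 2 lines farthest in genotype distance the values were 0.016 (permutation p = 0.344) and -0.016 (permutation p = 0.369). After removal of 3 components, lines closer in genotype were slightly closer in accessibility. The Spearman value was 0.051 (permutation p = 0.0354, adjusted p = 0.156) and the Pearson value 0.056 (permutation p = 0.0039, adjusted p = 0.0429), both adjusted over 22 values from 11 settings of this relation. Without the 2 farthest lines these were 0.044 (permutation p = 0.0720) and 0.054 (permutation p = 0.0140, adjusted p = 0.103), and without the libraries labelled DGRP_25185 and DGRP_29651 they were 0.061 (permutation p = 0.0250) and 0.071 (permutation p = 0.0003, adjusted p = 0.0066). Within blocks the relation did not pass a p of 0.05. Before removal of components the Spearman value was -0.147 in block 2 (permutation p = 0.438) and 0.0042 in block 3 (permutation p = 0.980). After it, the value was 0.010 in block 2 (permutation p = 0.930) and 0.047 in block 3 (permutation p = 0.637), and block 1 held too few lines. The closest genotypes were those of DGRP_25185 and DGRP_28176, DGRP_25201 and DGRP_28177, and DGRP_55030 and DGRP_55031, which differed at 1.249%, 3.85% and 5.05% of variants. Accessibility of these pairs after 3 components correlated at -0.061, 0.108 and 0.014 over regions, but the library labelled DGRP_25185, in the first pair, resembled another genotype more than its own (below), so that the first value does not describe close genotypes.

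For each library, accessibility at the caQTL regions was predicted from every line's genotype, with effects fitted without that library. This comparison was added after the data were seen. In 42 of 44 libraries the line's own genotype gave the highest correlation (median 0.538 over these 42, across regions, which are not independent). The library labelled DGRP_25185 correlated at 0.012 with the prediction from its own genotype, rank 15 of 44, and at 0.531 with that from DGRP_28265. The library labelled DGRP_29651 correlated at -0.010 with its own, rank 23, at 0.426 with DGRP_28123 and at 0.281 with DGRP_28153. Among the 42, the lowest correlation with the own genotype was 0.184, in DGRP_29652.

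**Figure D4:**
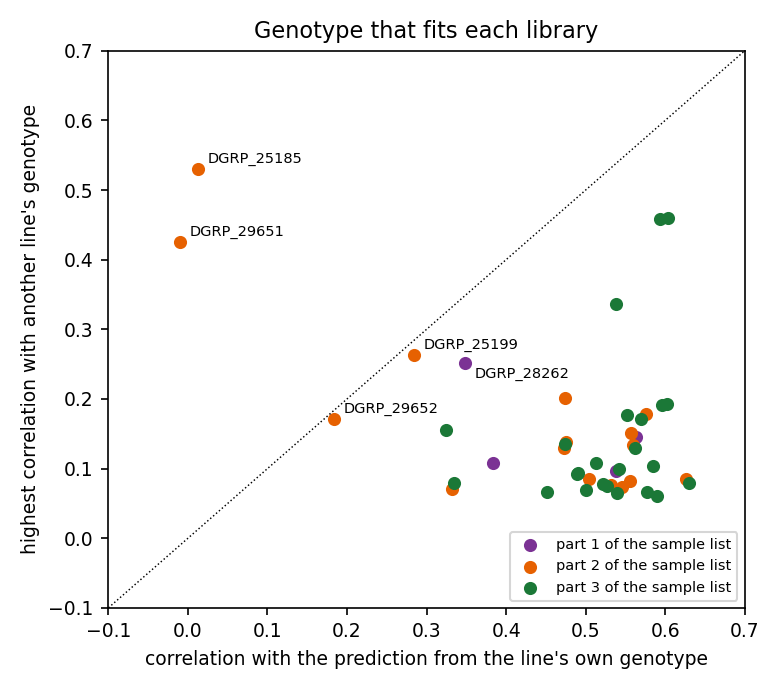
Each library by its correlation, across caQTL regions, with the accessibility predicted from its own line's genotype (horizontal) and by the highest correlation with another line's genotype (vertical), coloured by part of the sample list. Points above the dotted line of equality fit another genotype better: DGRP_25185 (0.012 and 0.531) and DGRP_29651 (-0.010 and 0.426).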

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

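Criteria were written beforehand for the comparison with other pairings of genotypes and libraries. The same holds for the test of the log scale for the share over all caQTL regions. The other tests in this part were chosen after the results were seen. Among these, the thinning of libraries and the test of where the allele calls came from had criteria written before they were run. They rest on the comparison of libraries with genotypes, which was added after the data were seen.

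The table of allele calls held a signal outside the comparisons above: regions where a line lacks calls were also regions where that line had little accessibility. In 668 combinations of a region and a line, at least 75% of the region's variants had no call. In 51.8% of them the line's accessibility lay under -1 on the log2 scale relative to the region's fitted level (346 of 668), against 0.744% where all variants were called. In 43.7% it was at most an eighth of the region's median, against 0.0713%, which is consistent with sequence that is missing in that line or too different to align. The criterion, written before this test was run, did not settle whether the calls were made from the reads of these very libraries. In the libraries labelled DGRP_25185 and DGRP_29651, regions without calls in their own genotype columns had a median residual of 0.046 (32 regions), which speaks against it. However, the regions without calls in the better-fitting columns had -0.37 (33 regions), short of the -0.5 of that criterion, with -1.53 for DGRP_29651 and -0.055 for DGRP_25185. Apart from the criterion, the own columns of DGRP_25185 and DGRP_29651 ranked 15 and 23 of 44 in fitting these libraries. If the columns carry the right labels, that argues against calls made from the reads of these 2 libraries. Near mthl8 at the left end of 3L (below), looked up after the data were seen, 12 lines had a count of 0. Of these, DGRP_28140 and DGRP_55015 lacked calls at 11.1% and 44.4% of the region's variants, and the others at 100%. Calls without a counted read argue against an origin in these reads for DGRP_28140 and DGRP_55015 at that region. No biological explanation was tested.

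The identity of 2 libraries is in doubt. With effects fitted without the library, the own genotype column ranked 15 of 44 for the library labelled DGRP_25185 and 23 of 44 for the library labelled DGRP_29651, so that each may hold another line. In a joint regression the library labelled DGRP_25185 had a weight of 0.815 ± 0.031 (SE) on DGRP_28265 and 0.078 ± 0.028 on its own genotype; these SEs treat linked regions as independent and are too small. The library labelled DGRP_29651 had weights of 0.439 on DGRP_28123 and 0.310 ± 0.019 on DGRP_28153, which suggests a mixture of both. Few reads are no explanation, since the libraries labelled DGRP_25185 and DGRP_29651 had 5.83 M and 7.41 M reads, above the median of 4.09 M. Of 41 other libraries thinned to 833273 reads, 0 fitted another genotype better. The shallowest library, DGRP_28238, first doubted in an exploratory check, had its own genotype at rank 1.

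The criteria for these libraries were revised after values had been seen. A first bound, own weight within 2 SE of 0, was missed by DGRP_25185, and a first bound for the mixture, a weight above those of all other libraries, would have failed because DGRP_25199 had a weight of 0.402 on the column of DGRP_25185 beside 0.394 on its own. DGRP_28262 had weights of 0.412 on its own genotype and 0.287 on DGRP_25186, and DGRP_29652 had 0.213 and 0.201 on DGRP_28238. The bound then used for the mixture was a weight over 2 SE above 0 and above 90% of those in the 42 libraries, a mark of 0.182. DGRP_25199, DGRP_28262 and DGRP_29652 also exceed it, as do DGRP_28233 (0.206) and DGRP_25187 (0.185). Some libraries exceed such a mark by construction, and whether these hold a mixture was not tested. The median weight on a second genotype was 0.088. Whether a library or a genotype column carries the wrong label was not tested. The libraries labelled DGRP_28265, DGRP_28123 and DGRP_28153 fitted their own genotype columns best, at correlations of 0.383, 0.531 and 0.555. That argues against an exchange of these columns with those of DGRP_25185 and DGRP_29651.

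The excess of lower alternative bases among caQTL regions (66.3%) has technical and biological candidates. Chance pairing of genotypes with libraries is excluded for the 2216 calls, since only 1 of 100 pairings, the real one, called as many, and the highest of the others called 2 regions. A bias of the log scale is excluded as the whole cause, because the top regions of other pairings reached at most 55.7%. By the logistic slope, the log scale is also excluded as the whole cause of the fall of the share with frequency. Only 1 of 100 pairings, the real one, had a slope as steep (-0.16 per 10 points of frequency, against -0.129 at the steepest of the others). By the odds ratio across 50% of lines it is not excluded, since 20 of 100 pairings, the real one included, reached the real value of 1.604. The log scale stays open as a part, because the share fell in all 99 drawn pairings (median slope -0.090). Lower accessibility of whichever base is rarer is excluded as the cause where the alternative base is the more common one, since 58.3% of called regions there had it lower, against at most 50.4% in the other pairings. Whether loss of reads with the alternative base in mapping adds to the fall cannot be told. Rarer lead bases came with a smaller net excess of alternative bases in the region (mean 3.28 against 3.60, permutation p = 0.0017), which argues against it, and within classes of that excess the odds ratio across 50% of lines was 1.669 (Mantel-Haenszel, 95% interval 1.37 to 2.03), but drawn pairings reached 1.80 without such classes and with genotypes unrelated to the libraries. Mapping loss stays open for the excess of 66.3% itself: the share was 60.3% where alternative lines carried a net excess of at most 1 alternative base, the lead included, and 80.1% where the excess was 9 or more, and insertions and deletions are not in the table of calls. Where over 80% of lines carry the alternative base, the share of 46.9% with it lower, equally 53.1% with the reference base lower, decides between neither mapping loss nor the rarer base in 64 regions. Selection against new variants was not tested.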

How the results depend on the processing

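The number of caQTL regions was 2216 and moved by over 1.5 times in 4 settings: 1159 without principal components, 1194 with log10 reads in their place, 834 in block 3 alone and 170 in blocks 1 and 2. The last 2 were chosen after seeing the data and hold 24 and 20 lines, which leaves fewer lines per base. Blocks 1 and 2 also hold the libraries labelled DGRP_25185 and DGRP_29651, and DGRP_29652, whose correlation with its own genotype was 0.184. The cause was not tested in any of these 4 settings. In the other settings the number of caQTL regions lay between 1552 (without the 11 lines of fewest reads) and 2363 (at least 3 lines per base). Of the 2341 regions called by edgeR on recovered reads, added after seeing the data, 2053 were shared with the main scan. The share with the alternative base lower stayed past the threshold in every setting, from 63.4% to 68.8%. The median coefficient of variation was 28.2%, and 17.9% as edgeR's biological coefficient with 3 components in the model, which removes counting error and those components by construction. The Spearman correlation of genotype and accessibility distance passed the threshold after removal of the 3 components (0.051), also without the libraries labelled DGRP_25185 and DGRP_29651 (0.061), and was -0.147 in block 2 alone, the last 2 added after seeing the data; neither Spearman value past 0.05 stayed so when adjusted over 22 values (adjusted p = 0.156 and 0.138), and the cause was not tested. Of 19 gene lists, 0 passed the adjusted threshold with regions as the unit, by nearest boundary or in a logistic model, and 6 with genes as the unit, where a gene with more regions has more chances of a call. The odds ratios near gene boundaries and on X and the position of lead variants kept their direction and their side of the threshold in every setting run. At the 71 named regions, 1632 of the 1753 values taken under alternatives stayed past the threshold, 121 did not and 0 reversed. The rank test is not among these alternatives. All but 6 named regions passed with every single line left out; Syt1 missed it without DGRP_55031, Rop without DGRP_25193, and Tl, Galphaq, Lsp1alpha and Mlc1 passed in 29, 40, 42 and 42 of 44. DESeq2 called 69 of the 71. An alternative restricted to single-base variants was not run, because all variants are of that kind. In reads simulated at the depth and spread of these libraries, 66% of 1.5-fold and 92% of 2-fold changes were recovered. Only 200 regions were changed there, against 2216 called in the real scan, so the adjusted threshold was stricter than in that scan. The simulated spread was estimated without genotype in the model. These rates therefore do not give the power of the real scan.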

Other observations

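The tests of neighbouring regions and of G or C bases were written down beforehand; the values at the end of 3L and at the roX genes were looked up after the data were seen.

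At the left end of chromosome 3L, accessibility was all or nothing. The region near mthl8 had counts under 10 in 25 of 44 lines, 12 of them at 0, and between 187 and 858 in the other 19, whose median was 465. Of the 25 low lines, 19 had no call at 75% or more of the region's 18 variants, against 0 of the other 19. The region nearest to CG43149, about 13.5 kb away from that gene, was under 10 in 16 lines, 10 of which lacked at least 75% of the calls, against 0 of the other 28, whose median was 508. Neither region had a testable variant, so the 2 appear in no caQTL count.

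Regions beside a caQTL region tended to move with it. Under 1 kb away, 66.5% of 1494 neighbouring regions had the same direction for the same variant (interval 64.1% to 68.9%), against 52.4% at 1 to 5 kb, 53.3% at 5 to 20 kb and 52.4% at 20 to 100 kb. Their effect was a median of 0.129 of that in the caQTL region. Lead variants may therefore act on adjacent regions as well, although neighbours can also share reads of 1 broad open stretch or a second linked variant, and pairs of regions are not independent.

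Bases also differed by composition. Among 1536 caQTL regions with a single lead variant between G or C and A or T, the G or C base had the higher accessibility in 62.6% (interval 60.1% to 64.99%), against 55.9% in regions not called (Fisher's exact test, odds ratio 1.32, p = 7.26e-07). The share was 75.2% where the reference base was G or C (interval 72.1% to 78.1%) and 47.3% where the alternative base was (interval 43.5% to 51.1%). Where both bases were of the same class, in 519 caQTL regions, the alternative base was lower in 67.6% (interval 63.4% to 71.6%) and higher in 32.4%, so the G or C base was higher more often than the excess of lower alternative bases alone gives, on either side.

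In DGRP_28202 the median log2 accessibility of X regions relative to autosomal ones was -0.51, the lowest of all lines, and the highest was 0.25 in DGRP_28123. Of 5 regions within 1500 bp of roX1 and roX2, genes of non-coding RNAs of the male dosage compensation complex, 1 inside roX1 (X, 3861069 to 3861645) was highest in DGRP_28202 at 750.6, against a median of 353.7 and a highest value of 538 in the other 43 lines. At the other 4 regions DGRP_28202 ranked 34, 35, 20 and 28 of 44. The labels give 1 brain of each sex per library, and whether this holds for DGRP_28202 is in doubt and was not tested.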
